A study of Mus musculus with 173 samples.

How the data were processed

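Single-cell RNA-seq libraries from the dentate gyrus of C57BL/6 mice were analysed from a single table of the whole series. Libraries were made from total RNA with the NuGEN Ultralow V2 protocol, per the labels' protocols. The authors deposited TPM (transcripts scaled to a common total) per gene, a unit in which expected read numbers are divided by transcript length and each library is scaled to the same total. Expression was estimated with RSEM against the mouse build mm9, per the submitters' processing notes, and the version, the aligner, the annotation and any filter on cells are not given in the sources used here. Every column summed to the same total within rounding. A row named Custom_eCFP1_gene shows that a transgene sequence was part of the authors' reference. RSEM divides reads that fit several genes among them by its model, so values of ribosomal proteins and their pseudogenes, tubulins, glutathione transferases, globins and predicted genes are uncertain. TPM keeps no information on depth, so no counts, depth or count test could be had. Of all values 78.5% were listed at 0. An exact 0 can be a failed estimate as well as an absent transcript: Gapdh, used by every cell, was listed at 0 in 2 libraries. A gene at 0 is therefore only said to be listed at 0.

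Libraries were put in the classes C, N and R by the first letter of their titles, with 142 C, 26 N and 4 R libraries. The labels list 173 samples and the table has 172 columns, of which 171 match 1 title each. The column C27 fits the titles of 2 samples, so it was used as a C library without a number of its own, and the planned comparison of those 2 samples was not run. The reference genome at hand was a later build than mm9, so it was not used and no coordinates are given; gene names are those of the table. Human samples were not part of the data.

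A library needed at least 1000 genes at a TPM of at least 1, which removed 0 libraries, and a gene had to reach a TPM of 1 in at least 5% of libraries, which kept 12007 of 23307 genes. Values were analysed as log2(TPM + 1), and differences on this scale understate changes of low genes. Doublets were not called, and libraries with markers of several cell types are described in the closing section. Before the data were examined, 38 gene lists (15 of cell types and 23 of processes, 568 genes in all) were fixed, together with the design, the rule for named genes and most alternatives. Of the lists, 35 had at least 3 measured genes; the ependymal, choroid plexus and fibroblast lists had fewer and gave no result.

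For C minus N and R minus C, the mean log2 value of each gene was subtracted between classes. For each list the median over its genes was set among the medians of 10000 random lists of the same size drawn from 20 bins of mean expression, as a description of these libraries. A list was called apart from other genes at a percentile of at most 2.5 or at least 97.5. Percentiles of different lists use the same random draws and are not p-values, and with 35 lists in each comparison some calls arise by chance. Shares of cells have exact Clopper-Pearson 95% intervals, which cover counting error only. No p-value was computed, since the labels name no animal and cells are not replicates.

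Clusters were made by Ward's method (8 clusters) on 15 principal components of the 2000 most variable genes, chosen by their variance above a lowess trend, with the list genes and eCFP left out. Names were given from the marker lists after the clusters were seen. For the order, genes outside the lists were split at random into 2 sets (seed 1). The first component of the 1000 most variable genes of each set ranked the 133 C cells in clusters 1 to 5, and it held 5.57% and 5.49% of the variance. List genes were set against the mean rank, and every other gene against the rank from the set that did not contain it, by Spearman's rho. The ranks from the 2 sets had a correlation of 0.95. Because the direction was set by the intermediate progenitor list lying above the stem cell list, the directions of those 2 lists relative to each other are not independent evidence. The rho values describe these cells and carry no p.

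The named genes follow a rule fixed in advance. It takes 13 set genes, the list member furthest from 0 in each cell type list, the 5 highest and 5 lowest genes outside the lists among those seen in most cells of the higher class, and, for the order, 2 members of each of 10 leading lists, 1 of each other list and 5 genes at either end. Some genes that the rule takes are not reported. A gene named by several parts of the rule counts under both. Leading genes of clusters are given only as what defines them. Single libraries picked out by their list means (in the report and in the closing section), and the level of at least 4, were chosen after their values were seen.

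Alternatives were pseudocounts of 0.1 and 10, no filter on low values, another scaling, other minimums of genes, 6 or 10 clusters, 30 components, list genes kept in, 500 or 2500 variable genes, all C libraries, regression on the number of genes detected, a path through 10 k-means centres, diffusion pseudotime, the order without the 2 cells furthest from its median, and each R library left out. Counts of alternatives that ended a call take the order without cluster 3 only in the direction of the full order. The rescaling sets the median of 2309 widely seen genes equal between libraries. It left out library N21, whose median of those genes was 0, and the other medians ran from 0.74 to 57.0 TPM, so it moves some libraries a great deal. For alternative clusterings a rule was needed to tell which clusters were not neurogenic, namely a mean of a neuronal, oligodendrocyte, microglial, endothelial or mural list at least 1 log2 unit above that of all libraries. The erythroid list was at first in that rule and was taken out after the clusters were seen, because it would have removed cluster 4, which had been named stem cell-like; with it, clusters not named by the rule held 113 and not 133 of the C libraries.

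Methods were tested on simulated data made by shuffling each gene among the C libraries and adding known changes. The shuffling removed the relations between genes, and no shared factor such as genes detected was added. The simulations therefore do not show how often unchanged lists are called in the real data. No class as small as R was simulated. With 2000 of 12007 genes changed, the recovered order had a rho of 0.97 with the true one, and with 200 genes changed only 0.19, with a correlation of 0.07 between the gene sets. An order with a high correlation between the sets is therefore needed before it is read. A shared factor such as genes detected could give a high correlation too. All 4 changed lists were called in each simulation. Of 27 unchanged lists 0 were called, except 4 in the class difference with 2000 changed genes. In that class difference the sign was right for 89.5% of genes changed by 1 log2 unit, 98.4% of those changed by 2 and 99.2% of those changed by 4; in the one with 200 changed genes the shares were 85.1%, 97.0% and 100%. In the order with 200 changed genes they were 67.2%, 70.1% and 74.2%, and with 2000 they were 97.0%, 99.9% and 100%. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, statsmodels 0.14.6, scanpy 1.11.5 and matplotlib 3.10.9.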

Results

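The series holds single-cell RNA-seq of the dentate gyrus of adult mice, the hippocampal region in which neural stem cells go on making granule neurons. The animals were C57BL/6 mice of 8 to 12 weeks. The labels describe each library as the RNA of a single cell, and the 172 libraries analysed fell into 3 title classes whose letters the labels do not spell out, namely N (26 libraries), R (4) and C (all others). The study set out to profile quiescent neural stem cells and their direct descendants and to order them by their transcriptomes. The table gives TPM, a length-scaled share of transcripts, so the sequencing depth of each cell is unknown. The number of genes at a TPM of at least 1 was 3734 ± 930.2 (SD between libraries) in C, 3512 ± 939 in N and 3199 ± 618 in R, with a range from 1600 to 7192. The labels name no animal, litter, date or batch, and cells of unknown animals are not replicates. Each class therefore counts as 1 sample, no test was possible, and all SDs below are between libraries.

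The row Custom_eCFP1_gene, which carries the sequence of the cyan fluorescent protein eCFP, set C apart from N and R. Its mean was 9579 ± 6310.3 TPM in C, 147 ± 284 TPM in N and 34.2 ± 49.3 TPM in R. The ratio of the C mean to the N mean was 65.3, and the ratio of the medians was 196. A TPM of at least 1000 was reached by all but 4 of the C libraries, by 1 of 26 N libraries and by 0 of 4 R libraries. The ranges overlapped slightly, with 6 C libraries below the highest N library (1306 TPM) and 2 N libraries above the lowest C library (482 TPM). The lowest N library still had 17.3 TPM, and N and R overlapped, with R1 (107.9 TPM) above the N median.

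**Figure D1:**
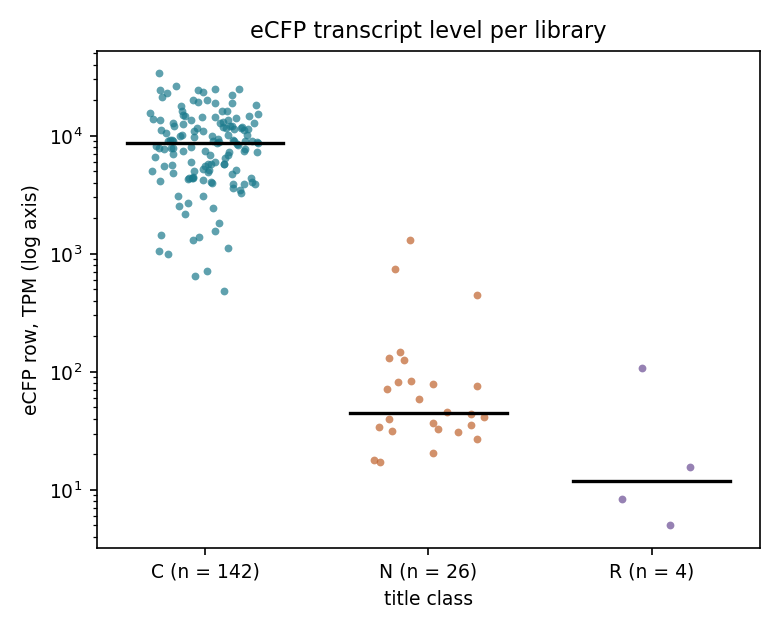
TPM of the eCFP row in each library (points, log axis) by title class, with the class median as a black bar; horizontal scatter within a class is random. The medians were 8739 TPM in C, 44.6 TPM in N and 12.0 TPM in R, and the C and N ranges overlap between 482 and 1306 TPM.

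The comparison of C with N asks which cell types the eCFP-high libraries hold. Genes of neural stem cells were far higher in C. Slc1a3, a glial glutamate transporter, averaged 11.22 ± 2.04 on the log2(TPM + 1) scale in C and 5.05 ± 2.32 in N (n = 26), a difference of 6.17. Hopx, a homeodomain protein found in quiescent stem cells, averaged 6.54 ± 3.41 against 1.08 ± 1.34. Aldoc, the aldolase of astroglia, averaged 10.86 ± 3.43 against 6.10 ± 2.79, and Apoe, a lipid carrier secreted by glia, averaged 10.93 ± 2.36 against 6.72 ± 3.05. Gfap, an intermediate filament of astrocytes and radial stem cells, averaged 5.44 ± 3.85 against 1.57 ± 1.69. Of the 13 measured stem cell genes 12 were higher in C, and the list's median difference of 4.17 lay at percentile 100 among 10000 random lists matched on expression. Nes, the filament gene often used to mark stem cells, was the exception: its means were 1.23 ± 2.08 in C and 1.34 ± 2.76 in N, and it reached a TPM of 1 in 29.6% of C cells (exact 95% interval 22.2 to 37.8) and 23.1% of N cells (8.97 to 43.6). In the clustering below, its mean TPM was highest in the vascular-like cluster 6 (86.2), which held 11 N and 2 C libraries. In the stem cell-like clusters 1, 2, 4 and 5 it ran from 1.56 to 32.6. Sox2, a stem cell transcription factor, reached it in 60.6% of C cells (52 to 68.7) and 30.8% of N cells (14.3 to 51.8).

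Genes shared with astrocytes followed the stem cell genes. The astrocyte list had a median difference of 1.83 (percentile 100), with 10 of 11 members higher in C, and Gja1, the gap junction protein connexin 43, averaged 7.36 ± 3.68 in C and 2.31 ± 2.39 in N. With the vascular-like, neuron-like and oligodendrocyte lineage-like clusters 6 to 8 left out, the astrocyte median was 0.76 and no longer called. That leaves 6 N libraries, among them N11 with an astrocyte list mean of 7.73. The list for transmitter uptake and ion homeostasis had a median of 1.75, with 12 of 12 members higher (0.73 and not called without those clusters), and the list for adhesion and matrix had 1.89, with 10 of 12. The antioxidant and metallothionein list had a median of 1.40, with 15 of 17 members higher in C, and lost its call with a pseudocount of 10 (0.85) and with log2 of mean TPM (0.64). Outside the lists, the genes furthest above N next to the eCFP row were 2610017I09Rik (difference 6.66), Tmem47 (5.60), Ppap2b (5.18) and Pla2g7 (5.11). Ppap2b, a lipid phosphate phosphatase, had a mean of 1251 TPM in C and 107.7 TPM in N.

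Genes of cycling cells and intermediate progenitors were also higher in C, by smaller amounts. All 16 measured S phase genes and all 20 genes of G2 and mitosis had a higher mean in C, with list medians of 0.79 and 0.77. In the clustering below, the excess lay mainly in cluster 3. The S phase list mean was 4.36 there, 0.80 to 1.45 in clusters 1, 2, 4 and 5, and 1.06 in N. For G2 and mitosis these means were 4.17, 0.43 to 0.99, and 0.74. Mki67, a marker of cycling cells, reached a TPM of 1 in 18.3% of C cells (12.3 to 25.7) and in 7.69% of N cells (0.946 to 25.1), and its means were 1.32 ± 2.60 and 0.39 ± 0.40. The intermediate progenitor list had a median of 0.71 (percentile 98.5), with 8 of 9 members higher, and was not called with a pseudocount of 10 or without clusters 6 to 8 (0.33 in each). Among them, Gadd45g averaged 2.88 ± 3.64 in C and 0.36 ± 0.90 in N, and Ccnd2, a G1 cyclin, averaged 5.16 ± 3.47 and 2.68 ± 2.77. Eomes, the transcription factor Tbr2 of intermediate progenitors, averaged 0.98 ± 2.17 and 0.35 ± 1.09. Sox11, a neurogenic transcription factor, averaged 2.56 ± 3.21 and 1.80 ± 2.44. For Mki67, Gadd45g, Ccnd2, Eomes and Sox11 alike, the difference was smaller than the SD between cells in C. The splicing list (median 1.2, 18 of 19 members higher), the chromatin list (0.81, 13 of 16) and the hedgehog signalling list (0.55, 7 of 7) completed the lists called higher in C. These last calls were less stable: chromatin lost its call under 5 alternatives, splicing under 4 and hedgehog signalling under 2.

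Oligodendrocyte and vascular genes were higher in N. All 8 oligodendrocyte precursor genes and all 11 oligodendrocyte genes had a higher mean in N, with list medians of -1.99 and -1.56 for C minus N. Olig1, a transcription factor of the oligodendrocyte lineage, averaged 0.93 ± 2.31 in C and 3.27 ± 3.73 in N, and Mbp, a protein of the myelin sheath, averaged 1.82 ± 1.86 and 4.2 ± 4.51. All 6 endothelial genes were higher in N (median -1.93), among them Ly6c1 at 1.16 ± 2.44 in C and 5.18 ± 5.65 in N. The mural list, for pericytes and smooth muscle, had a median of -0.85 with 5 of 6 members higher in N, and Acta2, smooth muscle actin, averaged 1.29 ± 1.99 and 3.55 ± 4.21. The SDs in N exceeded many of these differences. The immediate early and heat shock list had a median of -0.79, with 16 of 17 members higher in N. With clusters 6 to 8 left out, the endothelial median was 0.17, the mural median -0.0023 and the immediate early and heat shock median -0.11, none of them called. Only 6 N libraries remain there. Cluster 6 was named vascular-like from the marker lists, so the loss of the endothelial and mural calls was built into this setting. The erythroid list (-0.59, 4 of 4) and the neuroblast list (-0.25, 8 of 12) were called lower in C. The erythroid call was lost under 3 alternatives, among them a minimum of 3000 genes per library (median -0.00052). The neuroblast call was lost under 1, log2 of mean TPM (median -0.64). In the neuroblast list, Gap43, a growth cone protein, averaged 0.66 ± 1.81 in C and 2.63 ± 4.21 in N, and Dcx, a microtubule protein of immature neurons, averaged 0.40 ± 1.30 and 0.94 ± 2.30. Outside the lists, Pllp (difference -4.02), Itm2a (-3.85), Cryab (-3.74), App (-3.71) and Sptbn1 (-3.42) lay furthest below N.

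The median difference over all 12007 genes was 0.17, so list medians are read against matched genes and not against 0. On that footing the oxidative phosphorylation list (median -0.11) lay at percentile 0.010 and the cytosolic ribosome list (0.30, with 44 of 74 members higher in C) at percentile 0.00. After rescaling of the libraries the ribosome median was -0.62, again at percentile 0.00, so that list's sign depends on the scaling while its place below matched genes does not. With clusters 6 to 8 left out, which leaves 6 N libraries, its median was 0.81 at percentile 77.3, and it was no longer called. Lists not called were mature neuron (0.13), inhibitory neuron (-0.27), microglia (-0.12), Notch signalling (0.41), BMP and Id (0.34), Wnt signalling (0.31), growth factor receptor (0.57), glycolysis (0.34), fatty acid oxidation (0.48), lipogenesis (0.62), cholesterol synthesis (0.45), citric acid cycle (0.85), proteasome (0.78), lysosome (0.81) and cytoskeleton (0.49). Without clusters 6 to 8, glycolysis turned to -0.67 and was called low, and Notch signalling (0.63) was called high. Snap25, a synaptic protein, was lower in C (2.20 ± 2.86 against 4.02 ± 3.65), as was Cx3cr1, a microglial receptor (2.03 ± 1.43 against 2.86 ± 1.68). Pvalb (0.30 ± 1.04 against 0.93 ± 2.51) and Hbb-b1 (0.43 ± 1.91 against 1.37 ± 3.46) were near the floor in most cells. Stmn1, a tubulin-binding protein, was high in both classes (8.29 ± 3.82 and 6.92 ± 4.30).

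Clustering without the list genes and without eCFP gave 8 clusters. Clusters 1, 2, 4 and 5 were neural stem cell-like, with stem cell list means of 6.63 ± 1.19, 7.43 ± 1.04, 7.55 ± 0.75 and 6.15 ± 2.16. Their astrocyte list means were 3.56 ± 1.44, 4.27 ± 1.22, 4.37 ± 1.09 and 3.64 ± 1.39. Stem cells share markers with astrocytes, so the name does not tell these cells apart from astrocytes. Cluster 3 was intermediate progenitor-like, with the highest intermediate progenitor list mean of any cluster, 4.10 ± 1.58. Its stem cell list mean was larger still (4.90 ± 1.40), its S phase and its G2 and mitosis list means were 4.36 ± 2.0 and 4.17 ± 2.88, and its leading genes by fold were the cell cycle genes Rrm2, Aurkb, Cdkn3, Ube2t and Cenpa. The mean TPM of Eomes was nonetheless higher in cluster 5 (146.8) than in cluster 3 (65.4). Cluster 6 was vascular-like, with Fxyd5, Ramp3, Plscr2, Myh11 and Anxa3 leading. Cluster 7 was neuron-like, led by Sst, Slc6a15, Nefl and Resp18. Sst reached a TPM of 1 in 4 of its 12 libraries, the R libraries. The cluster also had P2ry12, a microglial gene, among its 10 leading genes. Its mature neuron list mean was 4.68 ± 1.74, and its stem cell list mean was close to that, at 4.43 ± 2.05. Of its 5 C libraries, C103, C63, C137 and C117 had stem cell list means from 5.30 to 7.54 and mature neuron list means from 3.48 to 6.10. Cluster 8 was oligodendrocyte lineage-like, led by Mog, Aspa, Gal3st1 and Gjb1. No leading gene of the 4 stem cell-like clusters was a listed marker. Each fold was taken against all other libraries, those of the other stem cell-like clusters included, so a marker that they share is unlikely to lead. In cluster 5 Cutc reached a TPM of 1 in 10 of 19 libraries and Ly6g6e in 9, while Gm2109, first in cluster 1, reached a TPM of 1 in 3 of 40 libraries.

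The 5 stem cell-like and progenitor-like clusters held 93.7% of the C libraries (exact 95% interval 88.3 to 97.1, counting error only). They held 6 of 26 N libraries, or 23.1% (8.97 to 43.6), and 0 of 4 R libraries, for which the exact interval reaches 60.2% and a limit of 3 counts allows a share of up to 75%. Cluster 6 held 11 N and 2 C libraries, cluster 8 held 6 N and 2 C libraries, and cluster 7 held 5 C, 3 N and 4 R libraries. Placement in a cluster did not always match the markers. Of the 6 N libraries in the stem cell-like and progenitor-like clusters, N11 alone had a high stem cell list mean (6.79, with an astrocyte list mean of 7.73). In the others that mean ran from 2.39 to 3.20, and N10 had an oligodendrocyte precursor list mean of 7.67, N1 of 4.78, and N8 and N9 neuroblast list means of 5.55 and 4.71. Likewise 6 C libraries had an oligodendrocyte precursor list mean of at least 4, and 4 of these lay in the stem cell-like and progenitor-like clusters. Cluster 4 contained 7 of the 14 C libraries with an erythroid list mean of at least 4 (list mean 2.13 ± 2.79 over its 20 libraries), from globin transcripts whose gene copies share reads.

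**Figure D2:**
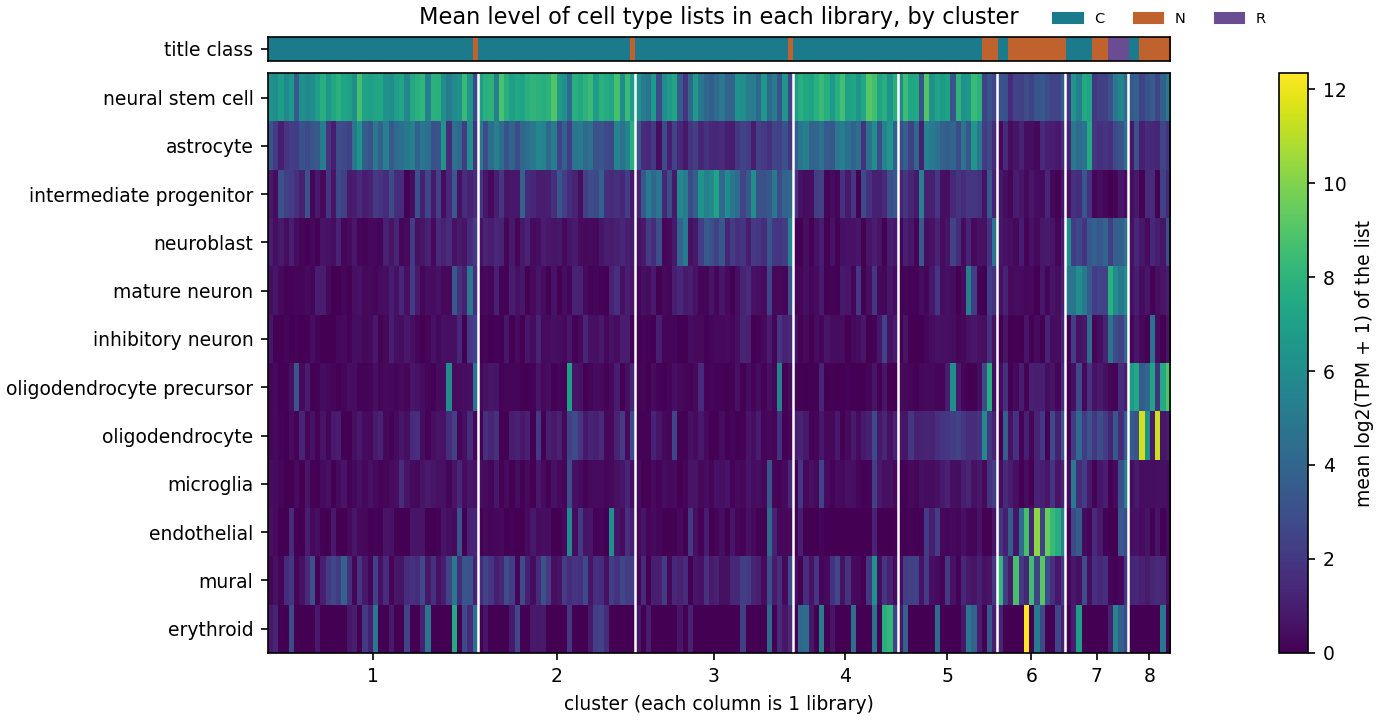
Mean log2(TPM + 1) of 12 cell type lists (rows, colour) in each of the 172 libraries (columns), grouped by cluster, with the title class in the upper strip. The stem cell list has its highest means in clusters 1, 2, 4 and 5 (6.15 to 7.55) but is also raised in clusters 3 (4.90) and 7 (4.43). The intermediate progenitor list has its highest mean in cluster 3 (4.10), and cluster 6 splits into libraries high in the endothelial or the mural list.

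The third question was how expression varied among the C cells when these were put in an order. The C cells of clusters 1 to 5 were ordered along the first principal component of genes outside the lists, with the direction set so that intermediate progenitor genes lay above stem cell genes. Some of these cells had high list means for other cell types. A mean of at least 4 was reached in 4 cells by the oligodendrocyte precursor list and in 3 by the endothelial list. The mural and mature neuron lists reached it in 2 each and the erythroid list in 13. Near the end of the order, C113 had a precursor list mean of 5.53 and C140 an endothelial list mean of 4.23. Both were high in the G2 and mitosis list (8.50 and 8.22). Some cells high in progenitor or cycling genes lay far from the end. C138 of cluster 5, at rank 34.5, had an intermediate progenitor list mean of 5.49 and a stem cell list mean of 3.18. C27 of cluster 1, at rank 75, had a G2 and mitosis list mean of 7.26 and a stem cell list mean of 3.52. Genes of protein synthesis and of the cell cycle were higher towards the end of this order, and genes of stem cells and astrocytes were lower. The cytosolic ribosome list went from a mean of 5.30 ± 0.94 in the first 27 cells through 6.08 ± 0.81, 7.0 ± 1.09 and 8.18 ± 0.99 to 9.52 ± 0.77 in the last 26, and 74 of 74 members had a positive rho (list median 0.34, percentile 100). Rps26 (rho 0.52) was at 2.74 ± 4.87 in the first 27 cells and 11.17 ± 1.66 in the last 26, with the caution that ribosomal protein genes share reads with many pseudogenes. The cell cycle lists stayed low over most of the order and were high at its end. The S phase list was at 1.03 ± 0.57 in the first bin, 1.66 ± 1.34 in the fourth and 4.45 ± 2.14 in the last, and the G2 and mitosis list at 0.73 ± 0.30, 1.07 ± 0.96 and 4.24 ± 3.11.

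Single genes followed these lists. Stmn1 had a rho of 0.57 and a Pearson r of 0.56 with the order, with means of 6.06 ± 3.29 and 12.14 ± 2.13 in the first 27 and last 26 cells. Hmgn2, a nucleosome-binding protein, had a rho of 0.58, and Hmgb2, a chromatin protein high in dividing cells, had 0.56. Among S phase genes, Rrm1, a subunit of ribonucleotide reductase, had a rho of 0.50 and Gins2, a part of the replicative helicase, had 0.47. Mki67 (0.42) reached a TPM of 1 in 0% of the first 27 cells and in 61.5% of the last 26, and Nusap1, a mitotic spindle protein, had a rho of 0.44. In the intermediate progenitor list, which had 9 of 9 positive members and a median of 0.25 (percentile 99.8), Ccnd2 had a rho of 0.52 and Sox11 of 0.44. Eomes had a rho of 0.17 and was at 0.25 ± 0.39 in the first 27 cells and 2.89 ± 3.42 in the last 26. By rho, Nes (0.20) and Sox2 (0.04) were not lower towards the end, and Dcx (-0.02) was seen in few cells at either end. The mean TPM of Sox2 was lower there, at 72.6 in the first 27 cells and 31.3 in the last 26. Outside the lists the most positive genes were Cdk4, a G1 cyclin-dependent kinase (0.56), Ptma (0.53), Gm12504 (0.51), Rpa1, a single-strand DNA-binding protein (0.50), and Rpl39l (0.50).

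Stem cell and astrocyte genes were level over the first 4 bins and lower in the last. The stem cell list was at 6.83 ± 0.67 in the first bin, 7.37 ± 1.22 in the fourth and 5.23 ± 1.74 in the last (list median rho -0.18, percentile 0.030, 9 of 13 members negative). The astrocyte list, at -0.19 with 10 of 11 members negative, had means of 3.74 ± 1.29, 3.75 ± 1.44 and 2.07 ± 1.19. The list for transmitter uptake and ion homeostasis had the lowest median, -0.21, with 11 of 12 members negative. Slc1a2, the main astrocytic glutamate transporter, had a rho of -0.49, with 9.66 ± 1.35 in the first 27 cells and 6.48 ± 2.22 in the last 26. Slc1a3 had a rho of -0.47, Fabp7, a fatty acid-binding protein of radial glia, -0.42, Aldoc -0.40 and Apoe -0.36, while Hopx (-0.18) and Gfap (-0.10) varied less with the order. Outside the lists the most negative genes were Cst3, the protease inhibitor cystatin C (-0.53), Gstm3 (-0.52), Ppap2b (-0.51), Gpm6b (-0.48) and Qk (-0.45). Gstm1 (-0.49), in the antioxidant list, and Gstm3 belong to a family of similar glutathione transferases whose reads can be split between members. Ntrk2, a neurotrophin receptor, had -0.35, Notch2 had -0.25, its ligand Jag1 -0.28, and Id4, an inhibitor of differentiation, -0.28. The Notch signalling list (6 of 10 members positive) and the BMP and Id list (7 of 12 positive) were not called as a whole.

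**Figure D3:**
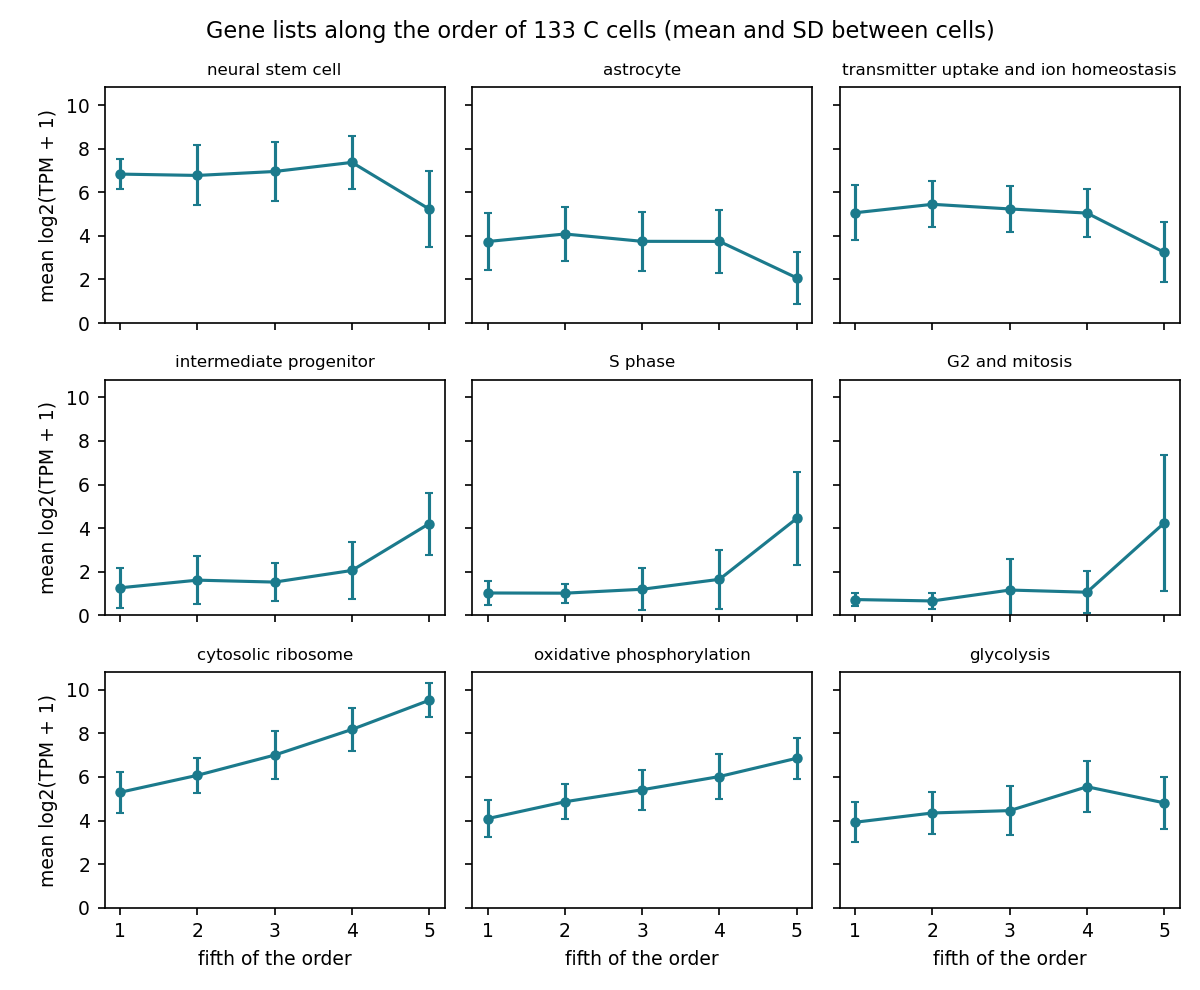
Mean log2(TPM + 1) of 9 gene lists over 5 consecutive bins of 26 or 27 C cells along the order; points are bin means and bars the SD between cells. The ribosome list climbs in every bin, from 5.30 to 9.52, while the stem cell list stays near 7 in the first 4 bins and is at 5.23 in the last, and the cell cycle lists are high mainly in the last bin.

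Other lists called high along the order were cytoskeleton (median rho 0.40, 13 of 14 members positive), proteasome (0.28, 24 of 25, Psmb3 at 0.36, not called on a path through k-means centres, 0.038), chromatin (0.27, 16 of 16) and splicing (0.25, 19 of 19, Snrpd1 at 0.49). Others called low were mature neuron (-0.08, Camk2a at -0.16), oligodendrocyte (-0.08), erythroid (-0.09, Hba-a1 at -0.14), Wnt signalling (-0.05), growth factor receptor (-0.04) and adhesion and matrix (-0.04, Sparcl1 at -0.37). Of these, Wnt signalling lost its call under 5 alternatives, and mature neuron, erythroid and growth factor receptor under 4 each, the last with a median of 0.024 over all C libraries; oligodendrocyte lost it under 2. In the Wnt signalling list Ctnnb1, beta-catenin, went the other way, with a rho of 0.35. Energy metabolism was mixed. The oxidative phosphorylation list had 34 of 34 positive members but a median of 0.17 at percentile 92.9, with Ndufa5 at 0.41 and Atp5b at 0.37. The glycolysis list was not called (0.12), and its members diverged, with Aldoa at -0.30 and Pkm at 0.38. Neither were fatty acid oxidation (0.08, Echs1 at 0.35 and Etfa at 0.16), citric acid cycle (0.11, Mdh2 at 0.34), lipogenesis (0.03, Scd2 at -0.25) and cholesterol synthesis (0.01, Sc4mol at -0.26). The remaining lists without a call were neuroblast (0.11, with Tubb3 at 0.34 and Elavl4 at 0.32), inhibitory neuron (-0.01, Pvalb at 0.21), oligodendrocyte precursor (0.02, C1ql1 at 0.10), microglia (0.05, Cx3cr1 at -0.22), endothelial (0.13, Cldn5 at 0.19), mural (0.08, Acta2 at 0.28), Notch signalling (0.02), BMP and Id (0.03), hedgehog signalling (0.00, Cdon at -0.09), immediate early and heat shock (0.00, Fos at -0.26), lysosome (0.00, Ctsz at 0.22) and antioxidant and metallothionein (0.08). The lysosome list, at percentile 3.0, was called low under 7 alternatives, among them rescaling (-0.14) and regression on genes detected (-0.099).

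The number of genes detected had a rho of 0.42 with the order, going from 3231 ± 768 in the first bin to 4099 ± 699 in the last, and eCFP had a rho of -0.23. The last bin consisted of 22 cells of cluster 3 and 4 of cluster 2, and without cluster 3 the direction of the order turned round (rho -0.93 with the full order), because its direction rests on that cluster. In that order, turned back to the direction of the full one, the ribosome list had a median rho of 0.18 (percentile 100), the S phase list 0.04 (17.1), the G2 and mitosis list -0.11 (0.00), the stem cell list 0.18 (95.1) and the intermediate progenitor list 0.02 (10.2). The astrocyte list had 0.08 (26.5), the list for transmitter uptake and ion homeostasis 0.06 (10.5) and the adhesion and matrix list 0.15 (80.9), none of them called. The splicing (0.12, percentile 55.3), cytoskeleton (0.11, 37.8) and chromatin (0.12, 71.7) lists also lost their calls there.

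The 4 R libraries differed from C in the genes of many cell types at once. Snap25 averaged 11.58 ± 0.87 in R (n = 4) and 2.20 ± 2.86 in C, and the mature neuron list had a median difference of 5.92 with 10 of 11 members higher. Sst, the neuropeptide somatostatin, stood at 854, 2153, 582 and 1249 TPM in R1 to R4 and at a mean of 0.196 TPM in C. The oligodendrocyte list (median 1.42, 8 of 11 higher), the microglia list (1.91, 4 of 6), the neuroblast list (1.91, 10 of 12), the inhibitory neuron list (1.64, 2 of 4) and the erythroid list (2.47, 4 of 4) were called higher too. Without R2 the erythroid median was 1.47 and not called, and the oligodendrocyte median, still called, was 0.71 without R1 or R2 and 0.56 without R3. The neuroblast median was 2.95 without R4. Mbp was at 478, 771, 899.6 and 1738 TPM in the 4 libraries, and Neurod1 at 299.9, 1069, 186 and 0 TPM. P2ry12, a microglial receptor, was at 977 TPM in R1 and 265 TPM in R3 and listed at 0 in R2 and R4, and Egfl7, an endothelial gene, was at 763 TPM in R1 and 272 TPM in R3 and listed at 0 in the others.

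Progenitor genes were low in R. The intermediate progenitor list had a median difference of -1.17 (percentile 0.10), with 9 of 9 members lower, and Ccnd2 was at 1.39, 1.30, 0.09 and 0 TPM in R1 to R4. Nes was listed at 0 in all 4 R libraries, and Sox2 in 3 of 4. Fabp7 averaged 4.97 ± 2.75 in R and 11.34 in C, while Aldoc (11.20 ± 0.42) and Apoe (11.29 ± 0.52) were at the level of C as log2 means. Their mean TPM was lower in R than in C, at 2434 against 6159 for Aldoc and 2625 against 3946 for Apoe. Eomes averaged 0.13 ± 0.26 in R, Sox11 0.90 ± 1.47 and Mki67 0.11 ± 0.18, and Dcx was at 142.4 TPM in R4 and listed at 0 in R1 to R3. Stmn1 was at 1089, 1854 and 1441 TPM in R1 to R3 and 2.31 TPM in R4, and Gfap (6.22 ± 3.79) and Hopx (4.59 ± 3.64) varied widely between the R libraries. Of other leading list members, S100b (difference 3.71, listed at 0 in R1) and Hba-a1 (4.32, listed at 0 in R3) were higher in R and Myl9 (-2.39) lower, while Pdgfra was at 119.5 TPM in R3 and at most 1.62 TPM in the others. The stem cell list was not called (median -1.28, percentile 4.37), but it was called low without R1 (-2.15), without R2 (-1.95) and with a pseudocount of 10 (-1.19). Some lists of energy metabolism were higher in R, with median differences of 2.49 for oxidative phosphorylation (31 of 34 members), 2.38 for glycolysis (13 of 14) and 1.75 for the citric acid cycle (9 of 13), while fatty acid oxidation was not (-0.30, 5 of 16, with -1.22 without R3 and 0.088 without R4). The citric acid cycle lost its call without R1 (0.99) or R2 (0.84). The ribosome list had a median of 0.78 (53 of 74) and lost its call without R4 (0.85) or with a pseudocount of 10 (0.44). Outside the lists, Sult4a1 (9.13), Stmn3 (8.72) and Atp6v1g2 (8.72), all active in neurons, were among the genes furthest above C, and after eCFP (-8.70), Cnn3 (-6.18), B2m (-6.13), Gm17644 (-6.09) and Sept2 (-5.79) lay furthest below it. The median over all genes was -0.36. Without R3 the microglia list had a median of -0.16 and was no longer called, and without R3 or R4 the inhibitory neuron list, with medians of 1.19 and 0.80, was not called either.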

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

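The test of a second cell in C libraries, the median among 9 of them and the count of cell classes in R libraries were chosen after the result was seen. In the 4 R libraries, 50 values were screened for a library that stood apart from the other 3 by its gap to the next; 6 were found, and chance gives about 1 in 20 for values spread normally, which TPM with many values of 0 are not. R3 stood apart in the mural list, with a mean log2 level of 1.90 against 0.26 in the next library. R1 stood apart in Sox2 at 1.23 TPM (the others listed at 0), in Sox11 at 7.48 TPM (next 0.35) and in eCFP at 107.9 TPM (next 15.7). R2 stood apart in Eomes at 0.43 TPM and R4 in Dcx at 142.4 TPM, with the others listed at 0 in both genes. For Sox2, Eomes and Dcx the rule is met by any single value above 0, and Eomes lies under a TPM of 1, so they carry little weight.

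The R libraries carried markers of several cell classes at once. Of 11 cell classes, the median R library had 6.5 at a list mean of at least 2 (R1 7, R2 6, R3 8, R4 4), against a median of 3 and a highest value of 5 in N and a median of 3 and a highest value of 8 in C. The lists do not mark fully separate cell types, since a gene such as Gfap is used by both astrocytes and stem cells. The counts are therefore not numbers of cell types. What the letter R stands for was not given, whether each R library holds the RNA of a single cell was not established, and no explanation was tested, since these counts are what drew attention to the libraries.

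The C libraries with the most genes (C103, C63, C137 and C117, with 6678 to 7192 genes) carried stem cell list means from 5.30 to 7.54 together with mature neuron list means from 3.48 to 6.10. More genes detected per library may account for this, but the values leave it open. Among 9 C libraries rich in stem cell genes and ranked 5 to 15 by genes detected, the highest mature neuron list mean was 4.89, above the 1.74 set beforehand from the lowest of the 4, yet the median was 0.54 and 2 of the 9 reached 1.74. RNA of a second cell may account for it too and was not settled, since 2 other C libraries with a stem cell list mean of at least 5 reached the lowest of the 4, up to 5.40. Without these 4 libraries every list of C minus N and R minus C had the same call. No biological explanation was tested.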

How the results depend on the processing

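The orders without cluster 3 or 4, the C libraries with over 6000 genes left out and the erythroid naming rule were added after seeing the data. No paired analysis was possible because no result comes from a test, and the numbers shared by titles of different classes do not mark pairs. The comparison of the 2 samples numbered C27 was not run, as they share a column. Over lists and alternatives, the standing of a list (called or not, whatever its median) was the same 317 times in C minus N, with 26 calls lost and 7 gained; in R minus C 297, 9 and 9; in the order 393, 29 and 25, with 1 reversed, taking the order without cluster 3 only in the full direction. The cause was not tested unless stated. The cluster counts stayed within 1.5 times, the erythroid rule included. Rescaling moved the all-gene median of C minus N from 0.17 to -0.04 and of R minus C from -0.36 to -0.24.

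In C minus N, the intermediate progenitor median was 0.33 and not called with a pseudocount of 10. The mural median was -0.41 and not called with a minimum of 3000 genes, which leaves 18 N libraries. With log2 of mean TPM the neuroblast median was -0.64, no longer called, and the inhibitory neuron median -1.65, newly called. Leaving out clusters 6 to 8 leaves 6 N libraries, and astrocyte (0.76), intermediate progenitor (0.33), endothelial (0.17), mural (-0.0023), erythroid (-0.81), hedgehog signalling (0.54), ribosome (0.81), splicing (1.11), immediate early and heat shock (-0.11), transmitter uptake (0.73) and chromatin (0.48) lost their calls, while glycolysis (-0.67) was newly called low and Notch signalling (0.63) high. Other lists newly called were lipogenesis without a filter (0.61), lysosome with a minimum of 3000 genes (1.02), and growth factor receptor (1.67) and cytoskeleton (-0.26) with log2 of mean TPM. In R minus C, the stem cell median was -1.19 and called with a pseudocount of 10, and the inhibitory neuron median -0.016 and not called without a filter. With 1 R library left out, medians ran from -2.15 to -0.98 for stem cell (called without R1 or R2), from 0.80 to 2.28 for inhibitory neuron and from -0.16 to 2.60 for microglia. S phase was called low with a pseudocount of 10 (-0.62), without a filter (-1.03) and rescaled (-0.94). Notch signalling was called low rescaled (-0.77) and without R2 (-1.07), and proteasome high rescaled (1.78).

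In the order, oxidative phosphorylation was called high after rescaling (0.15) and after regression on genes detected (0.20), and neuroblast was called high after that regression (0.14). With a TPM of 1 needed in 25% of ordered cells, neuroblast (0.32, 3 genes) was called high and Notch signalling (-0.12) low. Lysosome was called low under 7 alternatives, with medians down to -0.18 on the path below. The path through k-means centres had a rho of 0.13 with the main order and of 0.69 between gene sets, and on it neuroblast (0.17) was high and glycolysis (-0.14) and fatty acid oxidation (-0.13) low, while proteasome (0.038) and oligodendrocyte (-0.076) lost their calls. Without cluster 3 the order turned round. Stem cell (-0.18), intermediate progenitor (-0.020) and S phase (-0.042) lost their calls, neuroblast (0.063) was high and glycolysis (-0.20) low, and mature neuron (0.090), ribosome (-0.18) and proteasome (-0.19) reversed. Turned back to the full direction, stem cell (0.18), intermediate progenitor (0.020) and S phase (0.042) were without a call, neuroblast (-0.063) was low, glycolysis (0.20) high, and G2 and mitosis (-0.11) reversed.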

Other observations

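The tests of the order without cluster 3 turned to the direction of the full order were chosen after the result was seen. The predictions for genes detected and for the order without cluster 3 as it came out were written beforehand. The order without cluster 3 was itself added after the data were seen. Cluster 6 joined separate vascular cell types. Of its 13 libraries, 7 had an endothelial list mean of at least 4, 4 had a mural list mean of at least 4, and 0 had both. N26 combined an endothelial list mean of 8.77 with an erythroid list mean of 12.3. Cluster 8 likewise joined stages of the oligodendrocyte lineage: the precursor list exceeded the mature list in 5 of its 8 libraries, while N17 and N25 had mature list means of 11.4 and 11.5. C45 and C80, with eCFP at 11588 and 7778 TPM, had oligodendrocyte precursor list means of 7.36 and 6.74. C133 had a neuroblast list mean of 6.06 with a stem cell list mean of 2.02 and eCFP at 1568 TPM.

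The numbers in the titles followed eCFP. Within C, N and R the title number had a rho of -1 with the eCFP TPM, and the columns of the table stood in descending order of eCFP over all 172 libraries. The numbers are thus ranks, and replicate numbers shared between classes carry no pairing.

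The high ribosome, cytoskeleton, S phase and chromatin lists at the end of the order were weighed against technical causes. The number of genes detected does not account for them over all ordered cells: after every gene was regressed on it, the lowest percentile of the 4 lists was 99.99. A dependence on the cycling cluster 3 alone is a candidate explanation. Without it the lowest percentile was 0.00, but that order ran the other way and decides nothing. In the direction of the full order the cytoskeleton, S phase and chromatin lists reached at most percentile 71.7, as that explanation needs. This shows only that they rose no more than matched genes there. Over the first 4 bins the cytoskeleton mean rose from 5.27 to 7.23 and the chromatin mean from 2.38 to 3.48. Those bins held 0, 0, 2 and 5 cells of cluster 3, so the rise of these raw means was not confined to it. Some lists not called along the order rose over those bins too, as glycolysis did from 3.92 to 5.55. Others, such as neuroblast (0.71 and 0.72), stayed level. Genes detected rose from 3231 to 3859.5, so the raw means do not decide the question. In the order without cluster 3, in the full direction, the ribosome list stayed at percentile 100, which a dependence on cluster 3 alone forbids. The regression was not run without cluster 3, where genes detected had a rho of 0.39 with the order in that direction. An effect of genes detected on the ribosome, cytoskeleton and chromatin lists is therefore open among those cells.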
